A study of Homo sapiens with 6 samples.

How the data were processed

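Gene expression was measured on one-colour human expression arrays (SurePrint G3 Human GE, one array per hybridization) in subcutaneous tumours grown in nude mice from HT-29, an established human colon cancer cell line. The 6 arrays, all on 1 slide and read in 1 scan, fall into 3 of central and 3 of peripheral tumour regions. The series text says that separate hybridizations were made for each sample, so the replicates may be technical. Spike-in probes well above background on all 6 arrays had SDs of at most 0.051 (log2) between arrays of a region. The mean of the 25 tested hypoxia genes had SDs of 0.46 between central and 0.48 between peripheral arrays. These values argue against hybridizations of the same RNA within a region. Whether the arrays hold different tumours is not known, so p-values may not measure the spread between tumours.

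The deposited scanner output holds, per the file headers, the processed signal intensity of each spot after background subtraction and detrending, made with Agilent Feature Extraction 10.10, per the submitters' processing notes. These intensity values carry no normalization between arrays. The deposited signal table equals the processed signal times about 1 factor per array, between 2.08 and 2.35, and how the factor was set is not stated. The deposited ratio table holds the log2 of peripheral over central scaled signal for arrays with the same replicate number, per the file headers. The deposited change table holds 309 spots of that table, all with 3 absolute log2 ratios of at least 1; 544 spots of the ratio table meet this, and the rest of the authors' selection rule is not stated. Per the labels' protocols, the authors worked in GeneSpring and used Fisher's exact test with Benjamini-Hochberg adjustment.

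From the scanner output, control spots and spots marked as non-uniform or population outliers were left out, and log2 processed signals were scaled by subtracting each array's 75th percentile over the spots that are not controls. The spots of a probe were averaged. A probe was kept if it was well above background, as the scanner software calls it, on all 3 arrays of at least 1 region, and the probe with the highest mean stood for its gene. Of 62976 spots per array, 58717 were not controls; they held 42405 probes, of which 25368 were kept, standing for 14906 genes. No spot that was not a control was saturated. Symbols came from the array annotation matched by gene ID to a RefSeq gene table (assembly GRCh38.p14, used only for symbols and gene type) for 28801 probes and from the array annotation alone for 2453 probes, and 11151 probes had none. Chromosome bands are those of the array annotation, built on hg19.

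Regions were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8): a linear model per gene with moderated variances, two-sided, with Benjamini-Hochberg adjustment over the 14906 genes and a threshold of 0.05 on the adjusted p. A second count took the genes that also differed at least 2-fold. Differences are log2 peripheral minus central with the standard error (SE) of the model and n = 3 arrays per region. Prior and residual degrees of freedom came to 6.35. The number of arrays limits the precision.

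The 24 gene lists, their tests and the alternatives were chosen before the data were examined; the tests of KEGG pathways, of a single array as the cause, of the interferon scores and of the muscle transcripts were added afterwards. Lists with at least 5 tested genes were tested with camera (limma) at a preset correlation of 0.01 between genes, with adjustment over the lists; camera with an estimated correlation, fry and Fisher's exact test were run beside it. None of the list calls held with an estimated correlation or by fry. By Fisher's exact test on the genes past the threshold, 5 of the 7 held (hypoxia, glycolysis, oxidative phosphorylation, mitosis and DNA replication), while cholesterol synthesis (adjusted p = 0.0817) and the interferon list (adjusted p = 1) did not. The fry test asks whether a list's genes move one way on balance, and does not compare them with other genes. The genes named are the 10 largest rises and 10 largest falls among named genes past the threshold, well above background on all 6 arrays and with regions that did not overlap; the 3 largest bounds per direction; up to 4 members per list with the smallest p; and the members of the lists of other cell types. For a gene not well above background on any array of 1 region, the fold is given as a bound against the larger of the gene's signal and the dimmest well measured probe on each such array. The bound compares means over arrays and leaves out the spread between them.

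Arrays with the same replicate number deviated together from their region's means, with correlations across genes of 0.494, 0.377 and 0.166, all over the minimum of 0.1 set for pairing. Central replicate 2 and peripheral replicate 3, which differ in number, also exceeded it, at 0.161. Genes are not independent replicates, and the same number also marks the same row of the slide, so the pairing may come from the slide as well as from a shared tumour. Region coincides with the column of the slide. A model with the replicate number as a block was therefore run as an alternative.

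The other alternatives were normexp background correction (offset 50), quantile normalization, median scaling, a 75th percentile over probes well above background, no filter on dim probes, a filter on all 6 arrays, keeping the spots marked as outliers, averaging a gene's probes, testing every probe, a variance trend with a robust prior, the deposited scaled signals, and leaving out each array in turn. The files hold no mean pixel signal, so the normexp alternative used the median pixel signal. A slide or scan block was not run, since 1 slide and 1 scan held all arrays.

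The analysis was tested on simulated data with 200 changed genes among 14906. Of 50 genes changed at each size, 26 were recovered at a log2 difference of 0.5, 39 at 1, 47 at 2 and 49 at 3, and 18 unchanged genes were called. Of 11 simulated lists, the 1 changed list was recovered and 0 unchanged lists were called. The simulated genes were drawn independently, while the estimated correlation between genes reached 0.96 in a real list (interferon-stimulated genes). The simulation therefore cannot show how often the list test errs on the real lists.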

Results

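The arrays measured messenger RNA in central and peripheral regions of HT-29 tumours, with 3 arrays for each region. Between 63.0 and 67.7 percent of the spots on an array were well above background, and the 75th percentile of the processed signal lay between 852.6 and 944.5 units. For 721 probes printed in at least 5 spots, the median SD between spots of the same array was 0.06 to 0.07 (log2), and that between arrays was 0.10 in central and 0.09 in peripheral regions. The comparison asks which genes and gene groups differ in level between the edge and the core of these tumours.

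Genes of the hypoxia response were lower in peripheral than in central regions, and genes of mitosis and DNA replication were higher. NDRG1, a hypoxia-induced gene of differentiation and stress, fell by 2.09 on the log2 scale (SE 0.50, n = 3 arrays per region), and VEGFA, which codes for the main growth factor of blood vessels, fell by 1.70 (SE 0.32). CCNB1, the cyclin that drives entry into mitosis, rose by 1.06 (SE 0.17). In peripheral regions 10 of 22 genes of oxidative phosphorylation and 6 of 19 of cholesterol synthesis rose, 7 of 18 glycolysis enzymes fell, and 0 of 25 interferon-stimulated genes passed. Camera called these 7 lists, and none of the calls held with an estimated correlation.

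Of 14906 genes tested with limma, 3410 (22.9 percent) changed between the regions, 1757 of them higher and 1653 lower in peripheral regions. At least 2-fold changes were found for 228 genes, of which 76 were higher and 152 lower. This balance turned under median scaling, with 182 higher and 109 lower, and was 206 higher and 194 lower without central replicate 2. The regions did not overlap for 6859 genes (46.0 percent), where chance gives 10 percent. The count of changed genes fell with any 1 array left out, when fewer arrays were fitted. Leaving out central replicates 1, 2 and 3 gave 513, 3236 and 2 changed genes. Leaving out peripheral replicates 1, 2 and 3 gave 2215, 0 and 1212. Without central replicate 3 and without peripheral replicate 2, 4905 and 4239 genes still had an unadjusted limma p under 0.05. The count of 2-fold changes was 67 without central replicate 1, 400 without central replicate 2, 2 without central replicate 3 and 0 without peripheral replicate 2, and 105 with normexp background correction. It was also 0 without the filter on dim probes (5940 of 22325 genes with an unadjusted p under 0.05), and under median scaling, which moved the median of all genes from -0.02 to 0.11, 2883 genes were higher and 815 lower. With the authors' scaled signals the balance went the other way, with 1425 higher and 2234 lower, and 52 and 183 among 2-fold changes.

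The largest rises in peripheral regions were those of CELA3B, PI3, CTSE and AKR1B10. They were ranked among named genes past the threshold, well above background on all 6 arrays and with regions that did not overlap. CELA3B, a pancreatic-type elastase gene, rose from -4.03 ± 0.45 to -2.29 ± 0.41 (log2 signal relative to the array's 75th percentile, mean ± SD, n = 3), a difference of 1.73 (limma adjusted p = 0.0184), and its near-identical neighbour CELA3A rose 2.83-fold. PI3, which codes for the elastase inhibitor elafin, rose by 1.71 (adjusted p = 0.0384), and CTSE, the gene of the gastric protease cathepsin E, by 1.54 (adjusted p = 0.0183). AKR1B10, an aldo-keto reductase gene, rose by 1.54 (adjusted p = 0.0493) and its close copy AKR1B15 by 1.45 (adjusted p = 0.0475). The probes of such copies may bind both transcripts, so which of the pair changed is uncertain. IL1R2, the decoy receptor of interleukin 1, rose by 1.42, the Src-family kinase gene LYN by 1.36, the gastric mucin gene MUC5AC by 1.28 and ESCO2, a gene of sister chromatid cohesion, by 1.27. The 3 kept probes of MUC5AC gave differences from 0.09 to 1.28, and the 2 of ESCO2 gave 0.78 and 1.27. With normexp background correction the differences of CELA3B, IL1R2 and LYN were 0.92, 0.84 and 0.76, below 2-fold with the calls kept, and that of ESCO2 was 0.35 (adjusted p = 0.247, from 0.014 to 0.247 over the alternatives). The call of AKR1B10 was lost with quantile normalization, and those of AKR1B10 and AKR1B15 when every probe was tested.

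The largest falls, under the same conditions, included 4 members of the hypoxia list, ANGPTL4, NDRG1, COXFA4L2 and VEGFA. ANGPTL4, which codes for an inhibitor of lipoprotein lipase, fell from 0.30 ± 0.96 to -2.32 ± 1.23 (log2 signal, mean ± SD, n = 3), a difference of -2.63 (limma adjusted p = 0.0452). NDRG1 fell from 7.04 ± 0.60 to 4.96 ± 0.90 (adjusted p = 0.0329), and ENO2, the neuronal enolase gene, by 2.05 on the log2 scale (SE 0.37). COXFA4L2, a mitochondrial gene induced by hypoxia, fell by 1.88, and PGF, which codes for placental growth factor, fell by 1.86. MYOM1, a gene of the muscle sarcomere, fell by 1.81 (1.09 with normexp background correction), NXPH4 of the neurexophilin family fell by 1.75, CCDC183 fell by 1.72 (adjusted p = 0.0165) and the neurotrophin gene NTF4 fell by 1.69. The call of ANGPTL4 was lost when every probe was tested (adjusted p = 0.0518, from 0.014 to 0.143 over the alternatives).

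Some genes were well above background in 1 region only, and their folds are bounds on the difference of means, under the chosen processing only. The spread between arrays is not part of these bounds. HASPIN, a histone kinase gene of mitosis, was at least 2.38-fold higher in peripheral regions, C2CD4A at least 1.99-fold and the prothrombin gene F2 at least 1.80-fold. In central regions, the olfactory receptor gene OR6Y1 was at least 4.54-fold higher, the TNF receptor adaptor gene TRAF1 at least 2.45-fold and ZMAT1 at least 2.36-fold. OR6Y1 varied widely between central arrays (SD 1.23, log2), and its difference between the arrays of replicate 3 was -0.861. With normexp background correction all 6 kept their calls at smaller log2 differences, of 0.37 for HASPIN, 0.34 for C2CD4A, 0.285 for F2, -1.15 for OR6Y1, -0.54 for TRAF1 and -0.40 for ZMAT1, so these bounds depend on the processing. In all, 17 changed genes had such a bound with the brighter signal in peripheral and 13 in central regions.

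**Figure D1:**
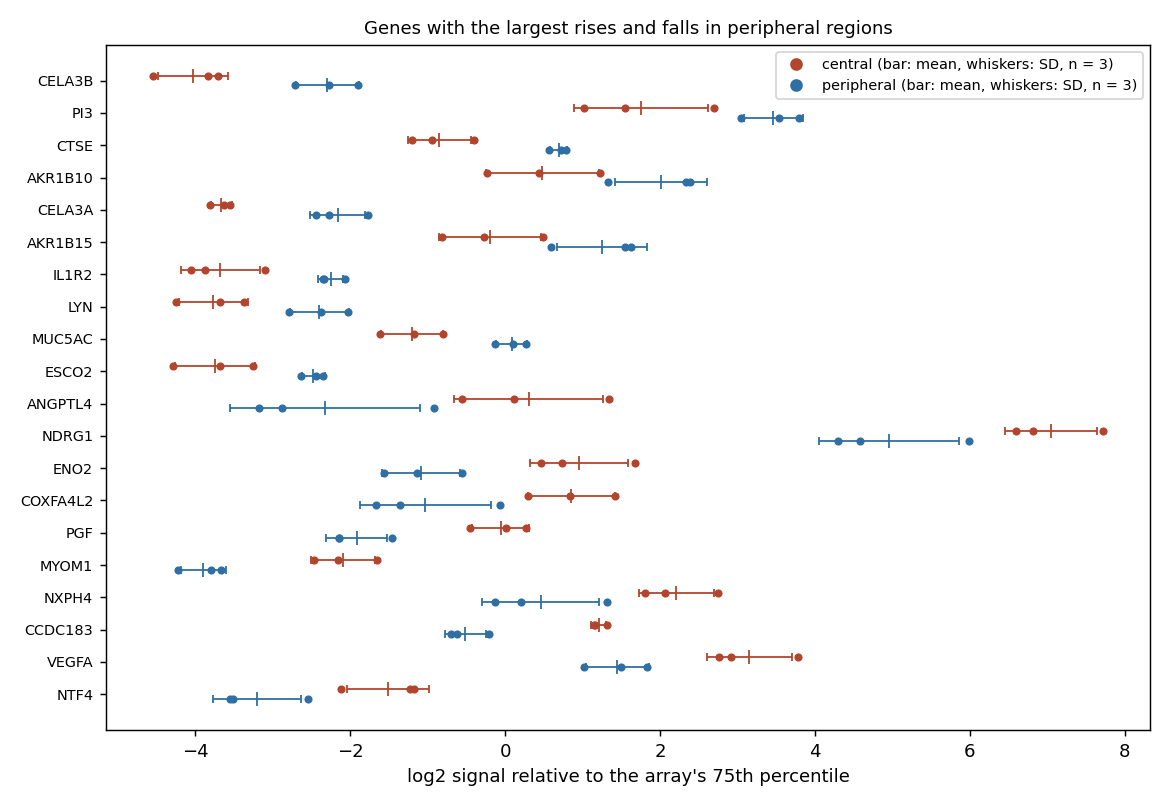
Signal of the 10 genes with the largest rises and the 10 with the largest falls in peripheral regions, as log2 relative to the array's 75th percentile (horizontal axis), with 1 point per array, the mean and the SD of n = 3 arrays per region. The regions do not overlap for any of these genes, which was a condition of their choice. NDRG1 lies highest, at 7.04 in central and 4.96 in peripheral regions.

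Of 25 tested genes of the hypoxia response, 19 fell, 0 rose and 6 did not pass, with a median of -1.33; adjusted over the list alone, 21 fell. CA9, which codes for the hypoxia-induced carbonic anhydrase of the cell surface, fell by 1.33 on the log2 scale (SE 0.24, n = 3), EGLN3, an oxygen-sensing prolyl hydroxylase gene, fell by 1.30 (SE 0.21), MXI1, an antagonist of MYC, fell by 0.90 (SE 0.15), and ZNF395 fell by 0.67 (SE 0.10). All 25 were lower in peripheral regions under each scaling tried. Of 18 glycolysis enzymes and partners, 7 fell and 11 did not pass, with a median of -0.56; adjusted over the list alone, 10 fell, and 11 fell with the replicate number as a block. Besides ENO2, ALDOC, an aldolase gene, fell by 0.95 (SE 0.21), PGK1, the phosphoglycerate kinase gene, fell by 0.78 (SE 0.18) and SLC16A3, which exports lactate, fell by 1.35 (SE 0.33). The hypoxia list was shifted down by camera (adjusted p = 1.23e-08; adjusted p = 0.748 with an estimated correlation), and so were the glycolysis enzymes (adjusted p = 0.0166; adjusted p = 0.956 with an estimated correlation). The glycolysis call was lost without central replicate 2 (adjusted p = 0.0865) and without peripheral replicate 1 (adjusted p = 0.0798), with a range of 0.000132 to 0.0865 over the alternatives.

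All 25 tested mitosis genes rose in peripheral regions, with a median of 0.91; adjusted over the list alone, 25 rose. BUB1, a kinase gene of the spindle checkpoint, rose by 0.92 (SE 0.16, n = 3), the mitotic kinase genes AURKB and PLK1 rose by 0.88 (SE 0.15) and 0.96 (SE 0.17). Of 27 genes of DNA replication, 26 rose, with a median of 0.93, or 0.90 with CDC6 at its bound; adjusted over the list alone, 27 rose. MCM7 and MCM3, parts of the replicative helicase, rose by 0.56 (SE 0.09) and 0.68 (SE 0.12), CDT1, a gene of origin licensing, by 1.05 (SE 0.18) and GINS1 by 0.96 (SE 0.17). The mean of the member that did not pass, CDC6, was at least 1.46-fold higher in peripheral regions (limma adjusted p = 0.068). All members of both lists were higher in peripheral regions under each scaling tried. Both lists were shifted up by camera: mitosis with adjusted p = 1.4e-12 (adjusted p = 0.748 with an estimated correlation) and DNA replication with adjusted p = 9.58e-13 (adjusted p = 0.748 with an estimated correlation).

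Of 22 genes of oxidative phosphorylation, 10 rose and 12 did not pass, with a median of 0.24; adjusted over the list alone, 16 rose. COX5A, a subunit gene of cytochrome c oxidase, rose by 0.41 (SE 0.07, n = 3), ATP5F1A of the ATP synthase by 0.39 (SE 0.09), and the complex I gene NDUFB8 by 0.27 (SE 0.06). All 22 were higher in peripheral regions under each scaling except quantile normalization, where 21 were, 3 rose and the calls of NDUFB8 and ATP5F1A were lost. Of 19 genes of cholesterol synthesis, 6 rose and 13 did not pass, with a median of 0.52; 12 rose adjusted over the list alone, and 15 with the replicate number as a block. ACAT2 rose by 0.95 (SE 0.20), DHCR7, the last reductase of the pathway, by 0.80 (SE 0.18), the lanosterol synthase gene LSS by 0.59 (SE 0.16) and NSDHL by 0.49 (SE 0.09); the call of LSS was lost when its probes were averaged or tested one by one. With all arrays, all 19 were higher in peripheral regions under each scaling except for 1 with the 75th percentile over probes well above background and 2 with the deposited scaled signals. With 1 array left out, 3 were lower without central replicate 1, 1 without peripheral replicate 1 and 2 without peripheral replicate 2. Both lists were shifted up by camera: oxidative phosphorylation with adjusted p = 1.11e-06 (adjusted p = 0.748 with an estimated correlation) and cholesterol synthesis with adjusted p = 3.62e-05 (adjusted p = 0.806 with an estimated correlation).

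Without central replicate 3 or without peripheral replicate 2, 0 members of each of these 6 lists passed. Only 2 and 0 of all 14906 genes passed in these fits, so the counts of 0 say nothing particular to the lists. The medians of the lists kept their direction in both fits. In these fits they were -1.11 and -1.21 for hypoxia, -0.37 and -0.55 for glycolysis, 0.84 and 0.85 for mitosis, and 0.90 and 0.87 for replication. They were 0.23 and 0.22 for oxidative phosphorylation, and 0.58 and 0.42 for cholesterol synthesis. Without central replicate 1, 2 hypoxia genes and 1 glycolysis gene fell, and 4 mitosis, 3 replication, 0 oxidative phosphorylation and 0 cholesterol genes rose. Without central replicate 2, 12 hypoxia and 4 glycolysis genes fell. Without peripheral replicate 1, 9 hypoxia genes and 1 glycolysis gene fell and 5 oxidative phosphorylation genes rose, and without peripheral replicate 3, 4 glycolysis genes fell and 4 mitosis, 2 replication, 1 oxidative phosphorylation and 1 cholesterol gene rose. Camera called 7 lists between the regions, but it called at least 7 in every other division of the 6 arrays into 3 and 3. Those divisions put arrays of both regions on each side and keep part of the difference between regions, so they do not show what camera calls without one.

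**Figure D2:**
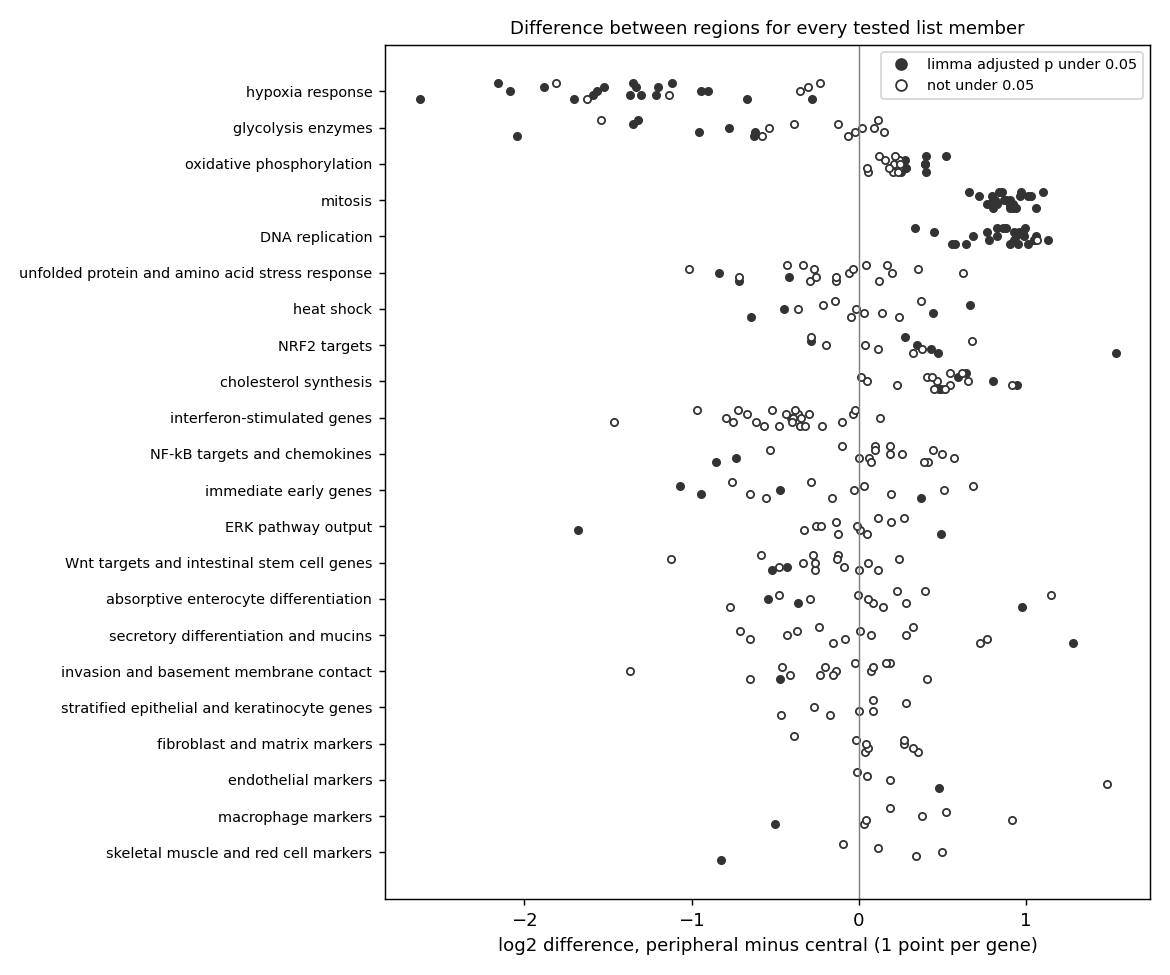
Difference between regions for each tested gene of the lists with at least 5 tested genes (horizontal axis, log2, peripheral minus central), with filled points for a limma adjusted p under 0.05. All 25 hypoxia response genes lie below 0 and all 25 mitosis genes above 0.

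Interferon-stimulated genes were lower in peripheral regions as a list, with a median of -0.40, though 0 of its 25 tested members passed (limma; 0 adjusted over the list alone, and 3 fell with the replicate number as a block, and 6 without peripheral replicate 1). IRF9, a transcription factor gene of interferon signalling, differed by -0.48 (SE 0.16, n = 3; limma adjusted p = 0.0694, and 0.0279 with the block). IFI44L and IFI44 differed by -1.46 (SE 0.54; adjusted p = 0.0955, and 0.0293 with the block) and -0.79 (SE 0.36; adjusted p = 0.149, and 0.0396 with the block), and IFIT2 by -0.67 (SE 0.31). In peripheral regions 24 members were lower, and 21 under median scaling. Camera gave adjusted p = 0.0214 for the list (adjusted p = 0.966 with an estimated correlation). The call was lost without central replicate 1 (adjusted p = 0.096) or 3 (0.135), without peripheral replicate 2 (0.16) or 3 (0.151), without the filter on dim probes (0.0654) and with the deposited scaled signals (0.0734), over a range of 2.6e-07 to 0.16. The list's scores, the mean of its centred genes on an array, overlapped between regions, at 0.44, -0.17 and 0.41 in central and 0.38, -0.50 and -0.57 in peripheral regions, and were lower in peripheral regions in all 3 pairs of the same replicate number.

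**Figure D3:**
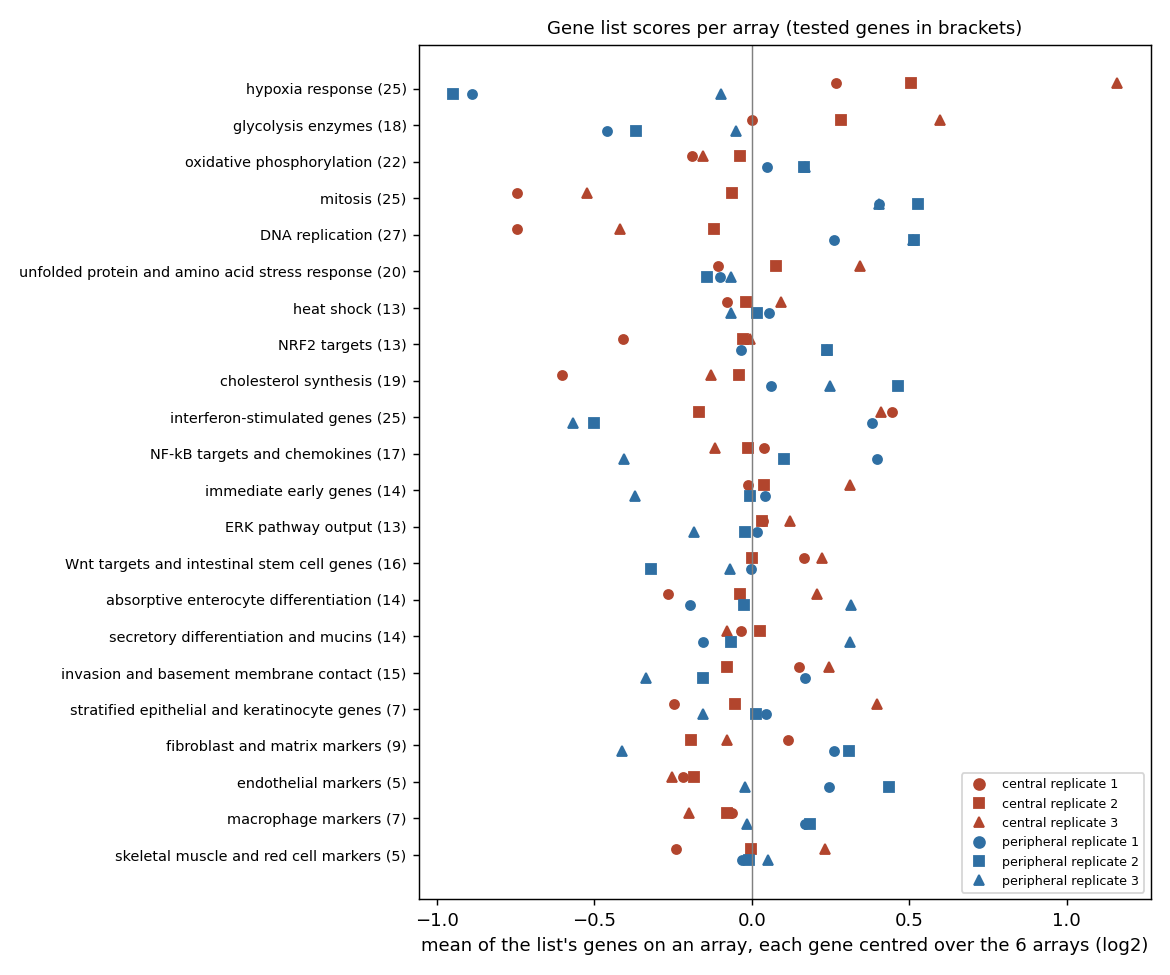
Score of each gene list on each array (horizontal axis, log2), the mean of the list's genes after each gene was centred over the 6 arrays, with central arrays in red, peripheral arrays in blue and a marker shape per replicate number. The hypoxia response scores lie between 0.27 and 1.16 in central and between -0.95 and -0.10 in peripheral regions, and the interferon scores overlap.

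The other lists of tumour programs were not called by camera with all arrays and the chosen settings. None of their members passed without central replicate 3 or without peripheral replicate 2, where 2 and 0 of all 14906 genes passed. Of 20 genes of the unfolded protein and amino acid stress response, 3 fell and 17 did not pass (camera adjusted p = 0.158; 3 fell adjusted over the list alone, and 8 fell and 1 rose with the block). Without central replicate 1, camera called this list (adjusted p = 0.0227, from 0.0227 to 0.389 over the alternatives) though 0 members passed, and 1 fell without central replicate 2, peripheral replicate 1 or peripheral replicate 3. The 3 that fell with all arrays were DNAJB9, a chaperone gene, which fell by 0.84 on the log2 scale (SE 0.20, n = 3), PPP1R15A, which restores translation after stress and fell by 0.71 (SE 0.17), and HERPUD1, a gene of protein degradation, which fell by 0.41 (SE 0.10). DDIT3, the stress transcription factor CHOP, differed by -1.02 (SE 0.31; limma adjusted p = 0.0603, and 0.0314 with the block). Of 13 heat shock genes, 2 rose and 2 fell (3 and 2 adjusted over the list alone; 4 rose with the block). The mitochondrial chaperonin gene HSPE1 rose by 0.44 (SE 0.11) and HSPA4L by 0.67 (SE 0.18), while HSPA1A and HSPA1B, near-identical copies, fell by 0.64 (SE 0.15) and 0.45 (SE 0.12). The median of the heat shock list was -0.02 (0.11 under median scaling) and its mean 0.00, and camera placed it up (adjusted p = 0.818). No heat shock gene passed without central replicate 1 or peripheral replicate 3, and 0 rose and 2 fell without peripheral replicate 1. Under median scaling the calls of DNAJB9, HERPUD1 and HSPA1B were lost, as were those of HSPA1B and HSPA4L when every probe was tested.

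Of 13 tested targets of NRF2, the regulator of the oxidative stress response, 5 rose, 1 fell and 7 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.0955). Camera called the NRF2 list without central replicate 3 (adjusted p = 0.0215), without peripheral replicate 1 (0.0367), without the filter on dim probes (0.0283) and with every probe tested (0.0127), from 0.0127 to 0.29 over the alternatives. With 1 array left out, 0 NRF2 targets rose without central replicate 1 and 1 without peripheral replicate 3, and 0 fell in any such fit. PGD of the pentose phosphate pathway rose by 0.35 (SE 0.08, n = 3), the sulfiredoxin gene SRXN1 by 0.43 (SE 0.08) and AKR1B10 as given above, while GCLM of glutathione synthesis fell by 0.28 on the log2 scale (SE 0.08; limma adjusted p = 0.0432, and 0.0569 with the block). NQO1, which also rose (by 0.28), lay outside the naming rule and was chosen after its value was seen. Of 17 NF-kB targets and chemokines, the feedback inhibitor gene TNFAIP3 fell by 0.85 (SE 0.18), TNFAIP2 fell by 0.73 (SE 0.16) and 15 did not pass (2 fell adjusted over the list alone). NFKB1 differed by 0.26 (SE 0.09; adjusted p = 0.0712, and 0.0445 with the block) and the adhesion gene ICAM1 by -0.53 (SE 0.22). No NF-kB target fell without central replicate 1 or peripheral replicate 3, and 1 rose without the latter. Under median scaling the call of GCLM was lost and NFKB1 passed.

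Among 14 immediate early genes, MYC, a transcription factor of growth, rose by 0.38 (SE 0.07, n = 3), FOSB fell by 0.94 on the log2 scale (SE 0.19; -0.625 with normexp background correction), KLF4 fell by 0.47 (SE 0.10) and CCN1 fell by 1.07 (SE 0.29; limma adjusted p = 0.0442, and 0.0541 with the block). The other 10 did not pass, and 1 rose and 4 fell adjusted over the list alone. Of 13 genes of ERK pathway output, CCND1, the G1 cyclin gene, rose by 0.49 (SE 0.09), the phosphatase gene DUSP5 fell by 1.68 (SE 0.39; -1.09 with normexp background correction) and 11 did not pass (1 rose and 1 fell adjusted over the list alone; 2 fell with the block). SPRY2 differed by -0.26 (SE 0.10; adjusted p = 0.0998, and 0.0435 with the block) and SPRED2 by -0.14 (SE 0.06). The ERK list's median was -0.01 and its mean -0.13, and the median was 0.01 with quantile normalization and 0.12 with median scaling, where the call of KLF4 was lost. Without central replicate 1, 0 immediate early genes rose and 1 fell, without peripheral replicate 1, 0 fell, and without peripheral replicate 3, 2 rose and 0 fell. No genes of ERK output passed without central replicate 1 or peripheral replicate 3, and 0 fell without peripheral replicate 1.

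Of 16 Wnt targets and intestinal stem cell genes, 2 fell and 14 did not pass (2 fell adjusted over the list alone, and 5 with the block; camera adjusted p = 0.124). Camera called the Wnt list without peripheral replicate 3 (adjusted p = 0.0332) and with every probe tested (0.0488), from 0.0332 to 0.238 over the alternatives, and 1 member fell without central replicate 1. AXIN2, a feedback inhibitor of Wnt signalling, fell by 0.52 on the log2 scale (SE 0.08, n = 3), and PROM1, which codes for the surface marker CD133, fell by 0.43 (SE 0.09). ZNRF3 differed by -0.33 (SE 0.12) and the transcription factor gene LEF1 by -1.12 (SE 0.47; limma adjusted p = 0.128, and 0.015 with the block). LEF1 was well above background on only 2 of the 3 peripheral arrays, and its difference lay between -1.53 and -0.558 over the alternatives. Of 14 absorptive enterocyte genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone; 2 and 3 with the block). GUCA2A, which codes for the gut hormone guanylin, rose by 0.98 (SE 0.11), the peptidase gene DPP4 fell by 0.36 (SE 0.09) and CDHR5 of the brush border fell by 0.54 (SE 0.15). CA2, a carbonic anhydrase gene, differed by 1.15 (SE 0.33; adjusted p = 0.0527, and 0.02 with the block). It was well above background on only 2 of the 3 central arrays, and its difference lay between 0.528 and 1.33 over the alternatives. Of the absorptive genes 0 fell without central replicate 1 or peripheral replicate 1, and 1 without central replicate 2 or peripheral replicate 3. The calls of PROM1, DPP4 and CDHR5 were lost under median scaling, and CA2 passed under it.

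Of 14 secretory and mucin genes, only MUC5AC rose (1 rose adjusted over the list alone; 2 rose and 3 fell with the block). REG4 differed by 0.77 (SE 0.24, n = 3; limma adjusted p = 0.0635, and 0.0495 with the block), TFF3, a trefoil factor gene, by -0.43 (SE 0.14; adjusted p = 0.0751, and 0.047 with the block) and MUC2, the main mucin of the colon, by -0.37 (SE 0.14). The 4 kept probes of MUC2 gave differences from -0.42 to -0.05. The list's median was -0.04 (0.09 under median scaling) and its mean 0.06. Of 15 genes of invasion and basement membrane contact, LAMB3, a laminin chain gene, fell by 0.47 on the log2 scale (SE 0.08) and 14 did not pass (1 fell adjusted over the list alone, and 4 with the block). MMP14, a membrane-bound matrix protease gene, differed by -0.41 (SE 0.15; adjusted p = 0.0864, and 0.0164 with the block), TGM2, a transglutaminase gene, by -1.37 (SE 0.57; adjusted p = 0.127, and 0.0222 with the block; its other probe gave -0.03) and PLAUR by -0.46 (SE 0.20). Of the secretory genes 2 rose without central replicate 2 or peripheral replicate 1 and 2 fell without peripheral replicate 3. Of the invasion genes 2 fell without peripheral replicate 1 and 0 without central replicate 1 or peripheral replicate 3.

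Markers of other cell types were few above background, and how far mouse RNA binds these human probes is not known from the files. Of 5 tested endothelial genes, VWF passed with a fitted rise of 0.48 (SE 0.13, n = 3; limma adjusted p = 0.0415), but was well above background on only 1 of the 3 central arrays, so the size of its rise is uncertain. The mean of TIE1 was at least 2.37-fold higher in peripheral regions, without passing (limma adjusted p = 0.0682, and 0.0141 with the block). With normexp background correction TIE1 differed by 0.55 on the log2 scale. CDH5 differed by 0.19, ESAM by 0.05 and EGFL7 by -0.01 (camera adjusted p = 0.158 for the list, with 2 rises adjusted over the list alone and 2 with the block). The endothelial scores were higher on each peripheral array than on any central array, from -0.02 to 0.43 against -0.26 to -0.18. TIE1 and VWF, both dim in central regions, carried most of this difference. The scores for mitosis, DNA replication, oxidative phosphorylation and cholesterol synthesis separated in the same way. Those for hypoxia, glycolysis, Wnt targets and ERK output separated the other way, the last 2 only barely. The nearest arrays lay at 0.0011 in central and -0.00119 in peripheral regions for Wnt targets, and at 0.0328 and 0.0173 for ERK output. Of 7 macrophage genes, CD68, a lysosomal gene, fell by 0.50 on the log2 scale (SE 0.11), while ITGAM, an integrin gene, differed by 0.92 (SE 0.29; adjusted p = 0.0666, and 0.0167 with the block), C1QB of complement by 0.52 (SE 0.22; adjusted p = 0.134, and 0.0381 with the block) and LAPTM5 by 0.38 (SE 0.16), with 1 fall adjusted over the list alone, and 2 rises with the block. Macrophage scores were also higher on each peripheral array, from -0.02 to 0.19 against -0.20 to -0.06. No endothelial gene passed without central replicates 1 or 3 or peripheral replicate 2, and with 1 array left out CD68 passed only without central replicate 2, where 1 other macrophage gene rose. The call of VWF was lost with normexp background correction, where it differed by 0.05, and with quantile normalization; under median scaling that of CD68 was lost while TIE1, CDH5 and ITGAM passed.

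Of 9 fibroblast and matrix genes 0 passed (0 adjusted over the list alone); THY1 differed by 0.35 (SE 0.18, n = 3), the collagen genes COL1A1 and COL1A2 by 0.32 (SE 0.23) and 0.27 (SE 0.24), and FAP by 0.27 (SE 0.23). Camera called this list without peripheral replicate 3 (adjusted p = 0.0332, from 0.0332 to 0.835 over the alternatives), and 1 member rose there and without central replicate 2. Of 7 genes of stratified epithelium, which skin would bring, 0 passed (0 adjusted over the list alone); IVL differed by -0.46 (SE 0.19), KRT10 by 0.09 (SE 0.08), SPRR1B by -0.27 (SE 0.27) and SPRR3 by 0.28 (SE 0.33). Of the 5 muscle and red cell genes, MB, the myoglobin gene, fell by 0.82 on the log2 scale (SE 0.15; -0.503 with normexp background correction) and 4 did not pass (1 fell adjusted over the list alone, and 0 without central replicate 3 or peripheral replicate 2). TNNT3 differed by 0.34 (SE 0.19), HBA2 by 0.50 (SE 0.45) and TNNC2 by 0.12 (SE 0.14). The median of the stratified list was 0.00092 and its mean -0.06, and the muscle list had a median of 0.12 and a mean of 0.01 while camera placed it down (adjusted p = 0.972). Of adipocyte genes 2 were tested: CFD fell by 0.46 (SE 0.12), and CIDEC differed by 0.42 (SE 0.14; limma adjusted p = 0.0756, and 0.0348 with the block; 1 rose and 1 fell adjusted over the list alone). Under median scaling the call of CFD was lost and CIDEC passed. The neutrophil gene tested, CSF3R, differed by -0.02 (SE 0.06).

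The deposited change table lists 162 gene symbols, of which 151 were tested here. Of these, 125 went the same way and passed the limma threshold, 114 also at least 2-fold, and 1 went the opposite way. The table was chosen on the same arrays, so it is not independent evidence.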

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

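No test in this part was chosen after the result was seen. Probes without a gene symbol stand outside the comparison of genes, and a signal in them is what brought this result here. Of 5215 such probes kept, 569 changed between the regions when every probe was tested with limma, 161 higher and 408 lower in peripheral regions, and 36 of them changed at least 2-fold (9 higher, 27 lower). Of all 25368 probes tested, which include these, 4297 changed and 320 changed at least 2-fold. Probes without a symbol thus changed less often than probes as a whole. What these probes measure is not stated in the files, and no explanation was tested. Groups of 3 arrays are too small to test for arrays that stand apart. On the main axis of variation between the arrays (60.3 percent of the variance), central replicate 2 lay at -9.4. Central replicates 1 and 3 lay at -31.5 and -25.8, and the peripheral arrays at 14 or above.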

How the results depend on the processing

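The alternatives here were planned, apart from the KEGG pathways, which were added after the data were seen. Camera called 6 to 9 lists under each scaling, filter, probe choice and variance model tried, and between 6 and 8 with 1 array left out, but 0 with an estimated correlation, which was 0.956 for mitosis and 0.787 for hypoxia, and 0 by fry. Leaving out each array in turn gave 0 to 3236 changed genes (0 to 1665 higher and 0 to 1571 lower in peripheral regions) and 0 to 400 changed at least 2-fold (0 to 206 higher, 0 to 194 lower); fewer arrays were then fitted. With no filter on dim probes, 0 genes changed and 0 changed at least 2-fold, higher or lower, with limma (5940 of 22325 had an unadjusted p under 0.05); the cause was not tested. Normexp background correction left 105 genes changed at least 2-fold (22 higher, 83 lower); it also replaced the processed signal, and the cause was not tested. Median scaling gave 2883 genes higher and 815 lower, and 182 at least 2-fold higher against 109 lower, with the median of all genes at 0.11. With the replicate number as a block, 4611 genes changed, 269 of them at least 2-fold, and camera called 7 lists; apart from the calls printed beside the genes and counts named, the block changed no other call of a list, except that fry called hypoxia, Wnt targets and muscle markers (adjusted p = 0.0246 each).

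Medians near 0 changed sign under some settings, and the cause was not tested. The heat shock median was 0.11 under median scaling and lay between -0.0545 and 0.108 with 1 array left out. The ERK median was 0.0112 with quantile normalization and 0.116 with median scaling (-0.146 to 0.00689 with 1 array left out). The absorptive median was -0.00355 with every probe (-0.147 to 0.193), and the secretory median 0.0899 with median scaling (-0.0835 to 0.0112). The stratified epithelial median was -0.0413 with normexp, -0.0173 with quantile normalization, -0.0234 with the 75th percentile over probes well above background, -0.17 with no filter and -0.0501 with the authors' scaled signals (-0.0564 to 0.0854). The fibroblast median lay between -0.000383 and 0.343 with 1 array left out. ESAM was -0.0213 with normexp and -0.00276 with the authors' scaled signals, CSF3R was 0.0695 with quantile normalization and 0.105 with median scaling, and KRT10 was -0.00601 with quantile normalization. With 1 array left out, SPRR1B lay between -0.546 and 0.0231 and SPRR3 between -0.0564 and 0.642. Of the named genes' values under the alternatives, 1604 kept their direction and their side of the threshold, 402 lost the call, 45 gained one and 7 changed sign. A slide or scan block was not run. Signal over background limits the dim genes: 59 tested genes were not well above background on any array of 1 region.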

Other observations

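The KEGG pathways, the effect of a single array, the interferon scores and the muscle transcripts were tests chosen only after the result was seen. Of 239 KEGG pathways in the deposited annotation, camera placed 32 higher in peripheral regions and 0 lower, and 0 were shifted with an estimated correlation. The broader KEGG pathways nearest to the hypoxia and glycolysis lists were not shifted: HIF-1 signalling (85 genes, 9 rose and 20 fell, median -0.02, adjusted p = 0.814) and glycolysis with gluconeogenesis (52 genes, 5 rose and 6 fell, median 0.02, adjusted p = 0.863). Nor was steroid biosynthesis (16 genes, 5 rose and 0 fell, adjusted p = 0.0807). Genes of the proteasome, which degrades tagged proteins, were among them: 22 of 41 rose and 0 fell, including PSMB6 by 0.44 and PSMB2 by 0.41 (adjusted p = 1.44e-09; adjusted p = 0.838 with an estimated correlation). Of 74 genes of ribosome biogenesis 26 rose and 4 fell, among the risers NOP56, a nucleolar protein gene, by 0.72 and POP1 by 0.82 (adjusted p = 1.74e-06; adjusted p = 0.838 with an estimated correlation). Of 50 genes of the Fanconi anaemia pathway of DNA repair 28 rose and 3 fell, with FANCA at 1.05 and BLM at 0.88 (adjusted p = 3.35e-06; adjusted p = 0.838 with an estimated correlation). A set of 95 genes named for lupus, of which 65 code for histones with near-identical copies, had 52 rises and 1 fall (adjusted p = 7.79e-12; adjusted p = 0.838 with an estimated correlation). The medians of these sets were above 0 under each scaling tried. Without central replicate 3 or without peripheral replicate 2, 0 members passed, as did only 2 and 0 of all 14906 genes. Without central replicate 1, 0 proteasome, 5 ribosome biogenesis, 9 Fanconi and 18 lupus set genes rose; without peripheral replicate 1, 11 proteasome genes did, and without peripheral replicate 3, 5, 9, 9 and 32. Of the 10 splits of the 6 arrays into 3 and 3, 4 gave at least 32 pathways (real value 32, highest other 65, or 35 among the splits that also part the 3 pairs). The count of 32 pathways thus did not stand out among the splits. The other splits keep part of the difference between regions, so they do not show what camera calls without one.

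Among 29 genes of the circadian rhythm pathway 7 fell and 1 rose, and the pathway was not called (camera adjusted p = 0.0541). With 1 array left out, 5 fell without central replicate 1, 4 without peripheral replicate 1, 4 without peripheral replicate 3, and 0 without central replicate 3 or peripheral replicate 2. The clock genes RORA, PER1 and CRY2 fell by 1.27, 0.69 and 0.53 on the log2 scale. EDN2, which codes for the vessel-constricting peptide endothelin 2 and was chosen after its value was seen, was lower in peripheral regions by a fitted -4.11 (SE 0.71, n = 3; limma adjusted p = 0.0194), and was well above background on 1 of the 3 peripheral arrays.

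Hypoxia genes were lower and cell cycle genes higher in peripheral regions. The 5 of 10 spike-in probes well above background on all 6 arrays differed between regions by at most 0.0256 after centring on their own mean of -0.0765. This was under the bound of 0.5 chosen beforehand for an effect of array position on the slide. The bound was not measured, and centring removes any shift shared by all probes, so this test cannot decide on an effect of position. The tables argue against a bias that follows signal level for these lists. Of 10000 random lists matched on mean signal, 0 had a median as extreme as the hypoxia list, and 0 of 10000 one as extreme as the mitosis or the replication list. A single array does not carry the pattern: each median kept at least 80.5 percent of its size with any 1 array left out. No table measured oxygen supply or growth, so a difference in them between the regions stays a hypothesis, which staining both regions for low oxygen and for dividing cells would test, while replicates of 1 tumour, the share of mouse RNA and effects of position that spare the spike-ins (region coincides with the slide's column) stay untested.

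The count of changed genes was at least as large as the real one in 1 of 10 splits of the arrays, the real one (3410, highest other 0), and that of genes changed at least 2-fold also in 1 (228, highest other 0). For the lists, all 10 splits gave at least the real 7 (highest other 14, also among the 4 splits that part the 3 pairs). For the 2 counts of genes, the splits were too few for a share under 0.05, and the count of lists did not stand out among them. Every other split also holds arrays of both regions on each side. It keeps part of the difference between regions and adds the rest to the spread within a side, so none of these counts decides.

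Interferon-stimulated genes were lower in peripheral regions as a list. Differences between arrays other than region could account for it, since the scores of the arrays overlapped. Within pairs of the same replicate number, however, the score was lower in peripheral regions in all 3, by -0.065, -0.334 and -0.98 (log2, SD 0.47), and the list was called with the replicate number as a block by camera (adjusted p = 0.00253, from 2.6e-07 to 0.16 over the alternatives) but not by fry (adjusted p = 0.552), nor by camera with an estimated correlation of 0.96 and no block (adjusted p = 0.966). The pair nearest to 0 differed by less than that SD, so this test does not decide, and a difference between regions stays open.

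The muscle genes MYL1 and KLHL41, chosen after their values were seen, were at least 1.58-fold and at least 1.38-fold higher in peripheral regions (limma adjusted p = 0.0183 and 0.0165), and TNNT2 was higher by 1.84 (log2), well above background on 1 central and 3 peripheral arrays. RNA from host muscle could be the source, and would bring other abundant muscle transcripts. The median difference of 8 such transcripts was 0.228 (SD 0.494). This lay below the bound of 1, set afterwards for host muscle, by more than the SD. Only 3 of the 8 were well above background on all 6 arrays, TNNC2 (0.12), DES (-0.09) and MB (-0.82). How well mouse muscle RNA binds these probes is unknown, so the test cannot tell host muscle and a change in the tumour cells apart. MYOM1 and MB went the other way, by -1.81 and -0.82.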
